A study of Homo sapiens with 12 samples.

How the data were processed

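Total RNA from human peripheral blood monocytes was measured on 12 one-colour Affymetrix oligonucleotide arrays, 6 from monocytes infected with human cytomegalovirus (HCMV) and 6 from mock-infected monocytes. Per the labels, cells were kept non-adherent for 4 h, and infected cells received virus at a multiplicity of infection of 15. Group and replicate number were taken from the sample labels. The titles of the mock samples call them biological replicates, and those of the HCMV samples give only a number. The labels give no donor, batch or scan day, so the p-values measure the spread between these samples, and a batch that followed the groups could not be told apart from infection. The treatment text attached to the HCMV samples also mentions pretreatment with an inhibitor of NF-kB, an inhibitor of phosphoinositide kinase or the solvent alone, without saying which sample received what. The text attached to the mock samples describes infection, so their group rests on their titles and source names.

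The deposited table holds an intensity for each of 12625 probe sets on each array, on a linear scale, and the submitters' processing notes name MAS5, with no version. From the deposited intensities, the mean of each array without the top and bottom 2% of probe sets lay between 2501.2 and 2501.6, so each array had been scaled to the same trimmed mean. Median intensity per array ran from 626.0 to 775.7. The table used here has no detection calls, and the number of arrays limits the precision. All 12 columns were used and 0 were left aside.

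Intensities were converted to log2(intensity + 55.9), where 55.9 is the 10th percentile of all values, so the fold change of a dim gene is understated. The 67 control probe sets were left out of the fit, which leaves 12558. Probe sets were tested if they exceeded the 40th percentile of their array on at least 6 arrays, which kept 7611. The comparison was HCMV minus mock in limma 3.58.1 under R 4.3.3 (lmFit, then eBayes with a mean trend, no block), two-sided, with Benjamini-Hochberg adjustment over the tested probe sets and a threshold of 0.05. A limma adjusted p is meant wherever an adjusted p of a gene is given.

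Gene names came from a platform annotation table, with symbols updated through gene identifiers. Of the 12558 probe sets, 10943 had 1 symbol, 545 had several and 1070 had none. For 10934 of the 10943 a current gene record was matched, and 9 kept the older symbol. No gene was named from a probe set with several symbols. A gene was represented by its brightest tested probe set, which gave 5440 genes, and 0 genes had probe sets past the threshold in opposite directions.

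Before the data were examined, 20 pathway lists and 7 lists of cell type markers were fixed. Each was tested on the representative probe sets with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, with adjustment over the lists of each kind. Counts of members past the threshold use the adjustment over all probe sets, and counts adjusted over the list alone are given beside them. The genes named are the 12 with the largest rise and the 12 with the largest fall among genes past the threshold. In addition, each list contributes up to 4 members past the threshold with the smallest p and up to 2 of the brightest members that were not. Other names are said to have been chosen after their values were seen. Genes that could reveal the sex of a donor are not reported.

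The difference in the 3' to 5' ratio of the GAPDH and ACTB control probe sets, a sign of RNA quality, was tested by an exact two-sided permutation over 924 assignments. The fit was tested on simulated data in which 200 of 7611 probe sets were changed. It recovered 6% of probe sets changed 1.41-fold, 72% of those changed 2-fold, 96% at 4-fold and 100% at 8-fold, and 7 of its 144 calls (4.86%) were false. Fewer probe sets were changed there than passed the threshold in the data, and the simulated noise was independent. Recovery and false calls in the data themselves may therefore differ. Alternatives covered the pseudocount, the filter, quantile normalization, centring on the median, the variance model, array weights, the replicate number as a block, the rule for several probe sets, stricter thresholds, the list test and leaving out each array. One more, without HCMV replicate 2 and mock replicate 2 together, was chosen after seeing the data.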

Results

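The series asked how HCMV, a herpesvirus that infects blood monocytes, changes the monocyte transcriptome at 4 h after infection. There were 6 arrays from infected and 6 from mock-infected cells. Log2 values correlated with r between 0.91 and 0.97 within the HCMV group and between 0.87 and 0.97 within the mock group, and between 0.78 and 0.91 across the groups. The first principal component held 40.4% of the variance and separated all 6 HCMV arrays from all 6 mock arrays. No pair of arrays within a group held identical values. In the HCMV group replicates 3 and 6 were closest (r = 0.966, next pair 0.949). In the mock group replicates 3 and 5 were closest (r = 0.967, next pair 0.938). These arrays had red cell marker means of at least 11.76, and the others at most 11.23. Their NK cell marker means were at most 10.83, and those of the others at least 10.90. Whether these arrays share a donor or preparation was not tested, so 6 independent samples per group cannot be assumed.

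Infected monocytes had more mRNA for many inflammatory cytokines (12 of 17 tested rose) and chemokine ligands (13 of 19), and 12 of 32 receptors typical of monocytes fell. With an estimated correlation the shift of the cytokine list was still called (adjusted p = 0.00788), and those of the chemokine ligands (adjusted p = 0.0603) and monocyte receptors (adjusted p = 0.069) were not. The largest rise was in IL6, a cytokine of the acute inflammatory response, whose log2 signal went from 8.62 ± 1.17 in mock to 16.98 ± 0.11 in HCMV (SD, n = 6 each), a difference of 8.36 ± 0.41 (SE, limma adjusted p = 9.2e-09). The largest fall was in PECAM1, an adhesion molecule of leukocytes and endothelium, from 13.79 ± 0.63 to 10.10 ± 0.28, a difference of -3.69 ± 0.26 (adjusted p = 3.64e-07). Of 5440 genes tested with limma, 498 were higher and 858 were lower in HCMV, and 4084 were not past the threshold. At a change of at least 2-fold the counts were 279 higher and 309 lower. At the level of probe sets, 712 were higher and 1113 lower, so 61.0% of the 1825 past the threshold were lower. Over all 5440 genes tested, 679 (12.5%) had no overlap between the groups' arrays, where chance gives 0.216%.

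The other 11 genes with the largest rise were, in log2 ± SE, F3 (5.80 ± 0.42), CXCL10 (5.25 ± 0.80), TNFAIP6 (4.91 ± 0.23), CSF3 (4.84 ± 0.38), CCL20 (4.33 ± 0.70), PTGS2 (4.30 ± 0.47), CCL18 (4.15 ± 0.42), CCL4 (4.13 ± 0.47), RSAD2 (4.05 ± 0.75), TNF (3.93 ± 0.28) and PTX3 (3.91 ± 0.42). F3 encodes tissue factor, which starts coagulation, PTGS2 makes prostaglandins and RSAD2 is an antiviral protein. The other genes with the largest fall were FUCA1 (-3.56 ± 0.47), a lysosomal fucosidase, CCR2 (-3.42 ± 0.48), the receptor of CCL2, VCAN (-3.40 ± 0.33), TGFBI (-3.34 ± 0.26), FPR3 (-3.20 ± 0.39), RNASE6 (-3.20 ± 0.45), CSF1R (-3.14 ± 0.25), ZNF467 (-3.09 ± 0.36), FGL2 (-2.94 ± 0.46), NOTCH3 (-2.92 ± 0.33) and FRAT2 (-2.85 ± 0.39). All 24 genes were separated on all 12 arrays. Averaging its probe sets gave ZNF467 -1.64, and without mock replicate 2 the value of CCL20 was 3.67. Without HCMV replicate 2 and mock replicate 2 together RSAD2 was at 3.22, CCL20 at 3.71 and CXCL10 at 4.64, and with array weights CCL20 was at 3.69 and CXCL10 at 4.57. The size of the change in dim genes moved with the pseudocount, from 4.51 to 6.08 for CXCL10, from 3.28 to 5.02 for CCL18, to 5.18 for F3 and from -3.53 to -2.21 for NOTCH3.

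**Figure D1:**
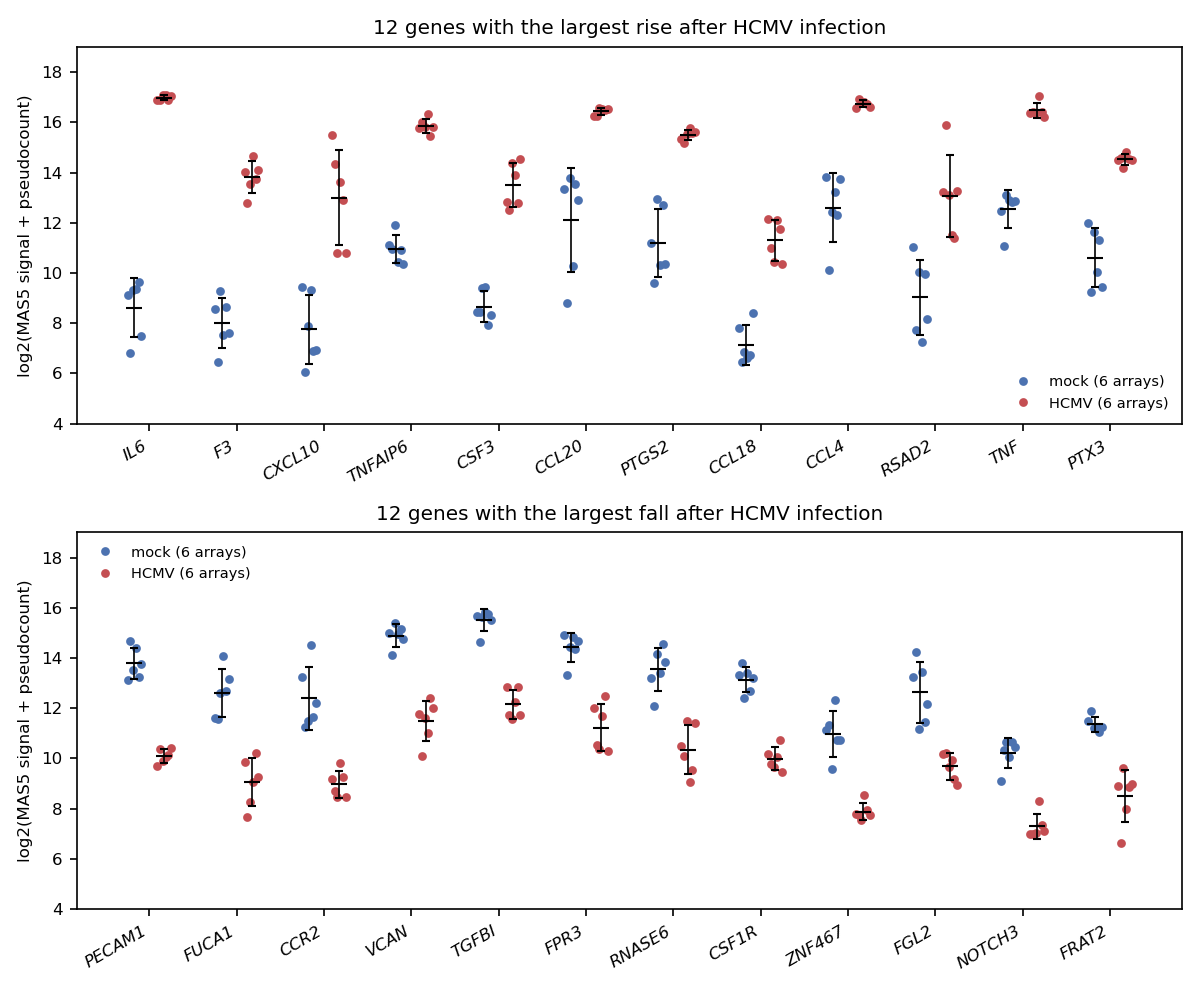
Log2 signal on each of the 12 arrays for the 12 genes with the largest rise (top) and the 12 with the largest fall (bottom). Points are arrays, blue for mock and red for HCMV, and black bars are mean and SD, n = 6 per group. IL6 sits between 16.88 and 17.10 in HCMV and between 6.82 and 9.64 in mock.

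Many chemokine ligands and inflammatory cytokines rose, and none tested fell past the threshold. Of 19 chemokine ligands tested, 13 rose and 0 fell (13 and 0 adjusted over the list alone), with a median of 2.29. Examples are CCL3 (3.30 ± 0.37), CCL4 and CXCL10, which attract monocytes and T cells. The camera adjusted p was 5.68e-10 (adjusted p = 0.0603 with an estimated correlation). CCL2 was at 1.79 ± 1.04 (adjusted p = 0.235), with mock replicate 2 at 9.13 and the other 5 mock arrays between 15.90 and 17.06, and without mock replicate 2 it was at 0.53 (adjusted p = 0.0333). CCL7 was at 1.53 ± 1.03 (adjusted p = 0.309), and at 0.40 without mock replicate 2 (adjusted p = 0.602). Of 17 inflammatory cytokines, 12 rose and 0 fell (14 and 0 adjusted over the list alone), with a median of 1.57 and a camera adjusted p of 1.18e-10. Besides IL6, TNF and CSF3 these included INHBA (2.94 ± 0.29), a subunit of activin. IL23A was at -0.10 ± 0.26 (adjusted p = 0.81).

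Chemokine receptors went both ways. Of 10 tested, 2 rose, CCRL2 (2.03 ± 0.26) and CCR7 (1.69 ± 0.29), and 2 fell, CCR2 and CXCR4 (-1.22 ± 0.20), with the same counts adjusted over the list alone. The median was 0.17, the mean -0.11 and the camera direction up, with an adjusted p of 0.606. Without mock replicate 2 the median was -0.02 and 3 receptors fell, and without HCMV replicate 2 also 3 fell. CCR1 was at -0.73 ± 0.33 (adjusted p = 0.119), against -0.996 without HCMV replicate 2 (adjusted p = 0.0168) and -0.97 without mock replicate 2 (adjusted p = 0.0252).

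Of 14 anti-inflammatory mediators, 6 rose and 3 fell (7 and 3 adjusted over the list alone). The feedback inhibitors SOCS3 (2.68 ± 0.20), SOCS1 (2.44 ± 0.27) and TNFAIP3 (1.46 ± 0.20) and the cytokine IL10 (2.10 ± 0.37) rose. The median was 0.59 and the camera adjusted p 0.00807 (adjusted p = 0.164 with an estimated correlation). DUSP1 was at 0.06 ± 0.19.

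Of 30 genes of the NF-kB pathway tested, 25 rose, 0 fell and 5 did not pass (28 and 0 adjusted over the list alone), with a median of 1.52 and a camera adjusted p of 4.31e-23. TRAF1, an adaptor of TNF receptors, rose by 3.42 ± 0.24, and TNFAIP6, F3 and TNF stood beside it. NFKBIE was at -0.25 ± 0.18 (adjusted p = 0.322). The mean over the list was 14.96 ± 0.10 in HCMV and 13.06 ± 0.41 in mock (SD, n = 6), and mock replicate 2 stood apart at 12.25.

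Of 35 classical (M1) markers tested, 22 rose and 1 fell (24 and 1 adjusted over the list alone), with a median of 1.68 and a camera adjusted p of 2.87e-16. IL6, TNF, PTX3 and INHBA had the smallest p, and CCL5 was at 0.68 ± 0.32 (adjusted p = 0.144). Of 25 alternative (M2) markers, 2 rose and 8 fell (2 and 9 adjusted over the list alone). TGFBI, FGL2 and LTA4H (-2.50 ± 0.38), an enzyme of leukotriene synthesis, fell, and CCL18 rose. The M2 median was -0.47 with a camera adjusted p of 0.0549, so the list was not called. It was 0.0337 without HCMV replicate 1, 0.00608 without mock replicate 2 and 0.0403 without mock replicate 4. The difference between the M1 and M2 lists was not tested. The M1 list shares 5 tested members with the interferon list, 5 with the NF-kB list and 4 with the chemokine ligands. IL6, TNF, PTX3 and INHBA are also in the list of inflammatory cytokines.

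Many interferon-stimulated genes rose, to different extents on the 6 HCMV arrays. Of 37 tested, 27 rose and 0 fell (29 and 1 adjusted over the list alone), with a median of 1.47. GBP1 (3.50 ± 0.47) and GBP2 (2.76 ± 0.25), which encode guanylate-binding proteins, and ADAR (0.99 ± 0.15), an RNA-editing enzyme, are examples. The camera adjusted p was 1.67e-14 (adjusted p = 0.0984 with an estimated correlation, which was 0.40 in this list). The mean over the list was 12.92 ± 0.68 in HCMV and 11.35 ± 0.34 in mock, and HCMV replicate 2 stood apart at 14.22. IFITM3 was at 0.22 ± 0.60 (adjusted p = 0.828).

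**Figure D2:**
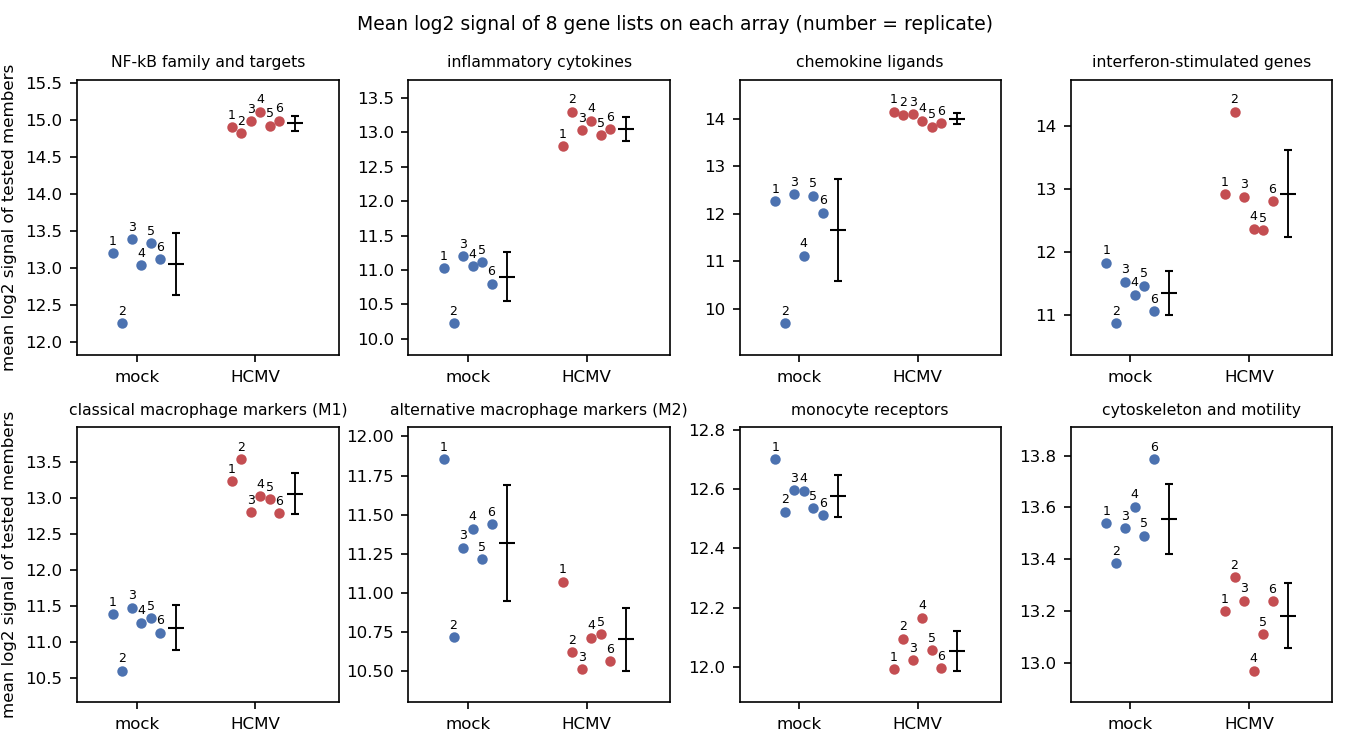
Mean log2 signal of the tested members of 8 gene lists on each array. Points are arrays, numbered by replicate, and black bars are mean and SD, n = 6 per group, and each panel has its own axis. For NF-kB genes the HCMV arrays lie between 14.82 and 15.11 and the mock arrays between 12.25 and 13.39.

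Immediate early genes did not move as a list. Of 26 tested, 7 rose and 3 fell (7 and 3 adjusted over the list alone), with a median of 0.17 and a camera adjusted p of 0.13. DUSP2 (2.06 ± 0.23), a phosphatase of MAP kinases, and IER3 (1.20 ± 0.12) rose, and the AP-1 subunits FOS (-2.69 ± 0.29) and JUND (-1.25 ± 0.15) fell. ZFP36 was at -0.32 ± 0.16 (adjusted p = 0.167).

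Some adhesion genes rose and others fell, and among cytoskeletal genes more fell than rose while most did not pass. Of 24 adhesion molecules, 6 rose and 4 fell (7 and 6 adjusted over the list alone). ITGB8 (3.13 ± 0.34), an integrin subunit, ICAM1 (1.94 ± 0.23), the ligand of leukocyte integrins, and NINJ1 (1.92 ± 0.14) rose, and PECAM1 fell. With other pseudocounts ITGB8 was between 2.46 and 3.74. The median was -0.16, the mean -0.01 and the camera direction up, with an adjusted p of 0.409. ITGB1 was at 0.04 ± 0.11. Of 39 cytoskeleton and motility genes, 2 rose and 11 fell (3 and 13 adjusted over the list alone), with a median of -0.24. MARCKSL1 (-2.02 ± 0.16), WAS (-1.14 ± 0.16), which drives actin branching, LASP1 (-1.02 ± 0.18) and EZR (-0.97 ± 0.17) fell. The camera adjusted p was 0.0104 (adjusted p = 0.164 with an estimated correlation). ACTB was at -0.02 ± 0.10.

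Of 18 matrix proteases and inhibitors, 6 rose and 4 fell (6 and 4 adjusted over the list alone), with a median of 0.08 and a camera adjusted p of 0.254. The collagenase MMP1 (3.29 ± 0.55), the stromelysin MMP10 (3.81 ± 0.39) and the membrane-bound MMP14 (1.95 ± 0.24) rose, and the inhibitor TIMP2 (-1.41 ± 0.19) fell. TIMP1 was at 0.01 ± 0.16.

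Of 16 anti-apoptotic genes, 8 rose and 0 fell (8 and 1 adjusted over the list alone), with a median of 0.51 and a camera adjusted p of 1.00e-05. TNFAIP8 (1.98 ± 0.15) and the kinases PIM2 (1.88 ± 0.19) and PIM1 (1.85 ± 0.21) rose, and MCL1 was at -0.15 ± 0.13 (adjusted p = 0.433). Of 20 pro-apoptotic genes, 4 rose and 4 fell (5 and 4 adjusted over the list alone), with a median of 0.08 and a camera adjusted p of 0.189. The inflammatory caspases CASP1 (1.89 ± 0.27) and CASP4 (0.98 ± 0.16), PMAIP1 (1.35 ± 0.27) and BID (0.90 ± 0.18) rose, and TNFRSF10B was at -0.05 ± 0.31.

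Some receptors typical of monocytes fell, and most did not pass. Of 32 tested, 12 fell, 1 rose and 19 did not pass (13 lower and 2 higher adjusted over the list alone), with a median of -0.43. CSF1R, the receptor of macrophage colony-stimulating factor (-3.14 ± 0.25), the Fc receptor FCGR3A (-2.47 ± 0.26), the endotoxin co-receptor CD14 (-2.28 ± 0.23) and the adaptor TYROBP (-1.18 ± 0.11) fell. FCER1G, an Fc receptor subunit, was at 0.01 ± 0.12 (adjusted p = 0.955). The camera adjusted p was 0.0407 (adjusted p = 0.069 with an estimated correlation, which was -0.012 in this list). The camera adjusted p was 0.0768 without HCMV replicate 1, 0.0551 without mock replicate 1 and 0.0528 without mock replicate 5, and ended above the threshold also at a filter on the 60th percentile (0.118) and with averaged probe sets (0.0634). With fry, which does not compare a list with other genes, the adjusted p was 5.78e-07. Of 11 genes of the MHC class II pathway, 0 rose and 2 fell (0 and 2 adjusted over the list alone), the peptide loaders HLA-DMA (-0.85 ± 0.15) and HLA-DMB (-0.65 ± 0.16), with a median of -0.10 and a camera adjusted p of 0.799. CD74 was at -0.01 ± 0.15.

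Among metabolic lists, that of oxidative stress genes was shifted up. Of 16 such genes and metallothioneins, 9 rose and 3 fell (11 and 3 adjusted over the list alone), with a median of 1.04 and a camera adjusted p of 3.53e-04. Thioredoxin, TXN (1.96 ± 0.22), the glutathione synthesis subunit GCLM (1.60 ± 0.21) and PRDX1 (0.72 ± 0.12) rose, and HMOX1 (-2.65 ± 0.29), which degrades heme, fell. FTL was at 0.20 ± 0.12. Of 16 sterol genes, 4 rose and 2 fell (4 and 2 adjusted over the list alone), with a median of 0.12 and a camera adjusted p of 0.096, and HCMV replicate 2 stood apart at a list mean of 10.94. LSS (2.34 ± 0.16), which closes the sterol rings, ACAT2 (1.59 ± 0.27) and HMGCS1 (1.53 ± 0.33) rose, SC5D (-0.82 ± 0.22) fell, but was at -0.62 without HCMV replicate 2 and mock replicate 2 together (adjusted p = 0.051), and IDI1 was at -0.10 ± 0.20.

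Of 20 glycolysis genes, 1 rose and 5 fell (1 and 6 adjusted over the list alone), with a median of -0.21 and a camera adjusted p of 0.285. PFKFB3 (1.97 ± 0.34), which raises the activator of phosphofructokinase, rose, and TPI1 (-0.81 ± 0.18), HK3 (-0.83 ± 0.21) and PFKFB4 (-1.12 ± 0.30) fell. PKM was at 0.10 ± 0.12. Of 41 cytosolic ribosomal protein genes, 0 rose and 1 fell, RPL22 (-0.47 ± 0.11), with the same counts adjusted over the list alone. Under quantile normalization 0 rose and 16 fell, with a median of -0.23, and under centring on the median 0 rose and 1 fell, with a median of -0.08. With the deposited scaling the median was -0.15 and the camera adjusted p 0.0549. That p ran from 0.00629 to 0.195 when 1 array was left out, and it was under the threshold without HCMV replicate 2, 3, 5 or 6 (0.0426, 0.0199, 0.0425 and 0.0418) and without mock replicate 1 or 3 (0.00629 and 0.0296).

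**Figure D3:**
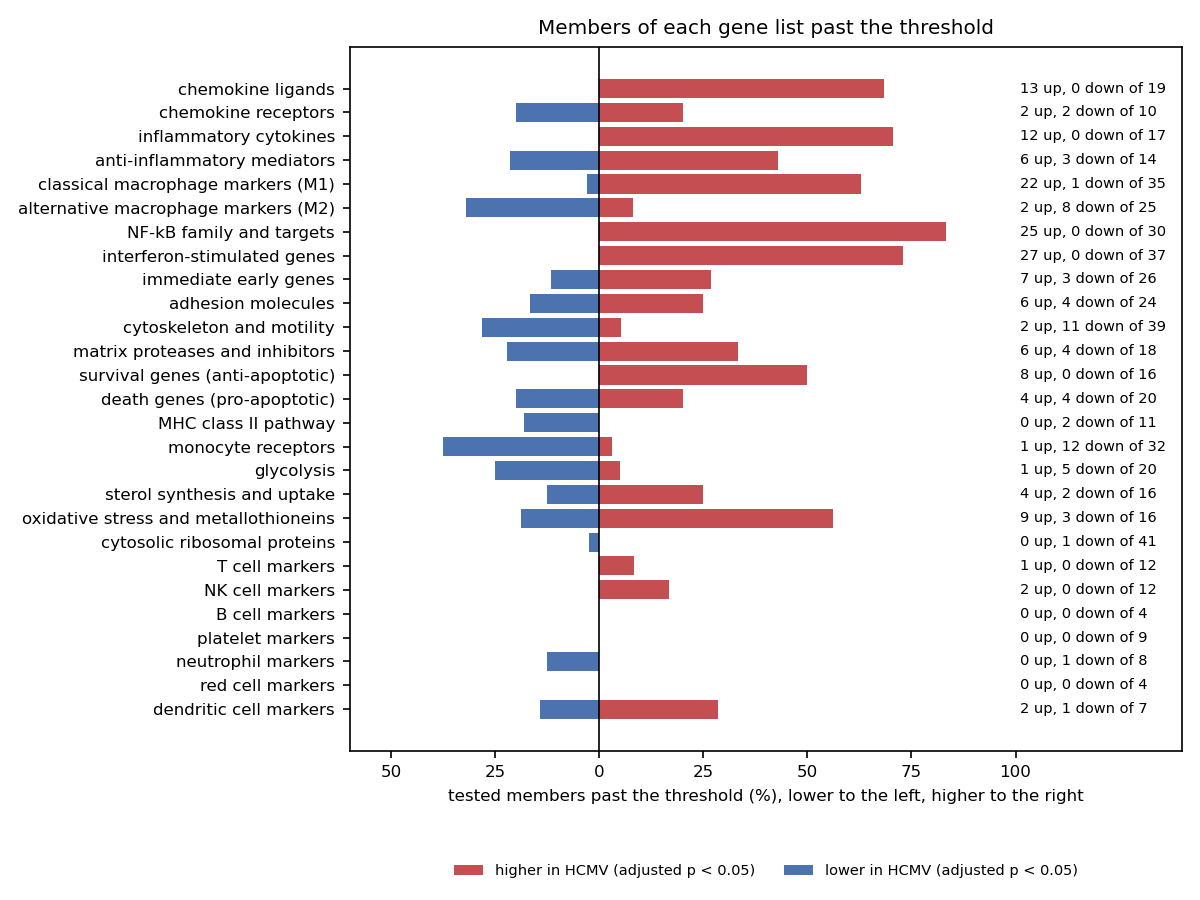
Share of tested members past the threshold in each of 27 lists, in percent, with members higher in HCMV to the right in red and members lower in HCMV to the left in blue, and the counts printed at the right. Of the 30 NF-kB genes 25 are higher and 0 lower, and of the 32 monocyte receptors 1 is higher and 12 are lower.

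With the main settings, markers of other blood cells did not shift as lists, and the lowest camera adjusted p of the 7 lists was 0.463, for NK cells. A marker list did pass the threshold in an alternative setting. Of 12 T cell markers 1 rose, CD8B (0.54 ± 0.18, adjusted p = 0.0387), and 0 rose adjusted over the list alone, with a median of 0.06 and a mean of -0.05. Without mock replicate 2, 0 T cell markers rose and 1 fell, with a median of -0.14. The call of CD8B was lost when HCMV replicate 1, 3, 4 or 5 (adjusted p = 0.0742, 0.069, 0.0864 and 0.0605) or mock replicate 2, 4 or 6 (adjusted p = 0.0736, 0.0744 and 0.0705) was left out, and also without a filter (0.0591), with array weights (0.0967) and without HCMV replicate 2 and mock replicate 2 together (0.0652). Of 12 NK cell markers 2 rose, GZMB (1.10 ± 0.22) and NCAM1 (0.76 ± 0.21), which lost its call with the replicate number as a block (adjusted p = 0.0597), with a median of 0.23, and GNLY was at 0.19 ± 0.42. None of 4 B cell, 9 platelet and 4 red cell markers passed, with medians of 0.23, 0.04 and 0.41. Without HCMV replicate 2, 1 platelet marker fell and the platelet median was -0.25. The platelet list had a mean of -0.06 and stood apart at 13.23 in HCMV replicate 2 and at 13.22 in mock replicate 6. Of 8 neutrophil markers 1 fell, FCGR3B (-2.82 ± 0.27), whose probe set is uncertain because the sequence of FCGR3A is almost the same, and the median was -0.06. Of 7 dendritic cell markers 2 rose, LAMP3 (2.51 ± 0.28) and CD83 (1.59 ± 0.23), and 1 fell, CLEC10A (-1.29 ± 0.35), with a median of -0.06, a mean of 0.30 and the camera direction up. Counts adjusted over the list alone were the same in the lists other than T cells.

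The 3' to 5' log2 ratio was higher in HCMV for both control transcripts, without passing the test. For GAPDH it was -0.08 ± 0.08 in HCMV and -0.18 ± 0.08 in mock (SD, n = 6, exact permutation p = 0.0519, adjusted 0.0628). For ACTB it was 0.10 ± 0.14 and -0.05 ± 0.07 (exact permutation p = 0.0628, adjusted 0.0628). Leaving out HCMV replicate 3 or 5 or mock replicate 2 or 3 took the GAPDH difference from 0.10 to 0.12 with an exact p between 0.0325 and 0.0455. For ACTB, leaving out HCMV replicate 2 (exact p = 0.00433) or mock replicate 1 or 2 (exact p = 0.0455 and 0.0498) also passed. With the estimated correlation the camera calls held for inflammatory cytokines, M1 markers, NF-kB genes and survival genes (adjusted p = 0.00788 each) and for oxidative stress genes (adjusted p = 0.0376). These lists overlap as fixed, so the calls are not independent. TNF is in the cytokine, M1 and NF-kB lists. The NF-kB list shares BCL2A1, BIRC2, BIRC3, CFLAR and IER3 with the survival list, IL1B with the cytokines and SOD2 with the oxidative stress list. Besides the genes named above, IL15 and TNFSF10 are in both the cytokine and the M1 list.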

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

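The tests of the scaling of HCMV replicate 2, of the share of monocytes and of the inhibitors were chosen only after the results were seen, and the tests of other splits, of the interferon list without HCMV replicate 2 and of the scaling between arrays were set before their own outcome was seen, but from patterns and counts already seen in the same data. For the scaling of HCMV replicate 2 and the share of monocytes the criterion itself was also replaced after its outcome was seen, 2 times for the former, as stated at each.

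Of 100 splits of the 12 arrays drawn with the real one, 1, the real one, gave as many probe sets past the threshold. The real split gave 1825 and the highest other split gave 9, which argues against a random split of the arrays as the source of that count. With 100 splits the test cannot go below 1 in 100. The other splits mix HCMV and mock arrays, so the difference between the groups adds to their spread and keeps their counts low.

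The mean of interferon-stimulated genes was far above the other HCMV arrays in HCMV replicate 2, at 14.22 against 12.35 to 12.92. Without that array 24 of the 27 higher genes were still higher, IFI16, MX2 and TRIM22 lost their call, IFITM2 was lower (-0.67) and the median of the 37 genes went from 1.47 to 1.11, which argues against that array as the whole cause of the calls. After quantile normalization its list mean was still 1.51 log2 above the mean of the other 5 HCMV arrays, against 1.55 log2 as deposited. All 27 higher genes were still higher both then and after centring on the median. The median over tested probe sets of that array lay only -0.032 log2 from the other 5, so neither step could take away much of the excess. No conclusion on the scaling of that array is drawn from them. The excess after quantile normalization is the third criterion used. By the first, in units of SD, the scaling had come out as a possible cause, since the mean of the other 19 pathway lists lay 4.54 SD, or 0.07 log2, above the other 5 arrays. The second, the median over tested probe sets, decided nothing, since the scaling to one trimmed mean largely fixes it. No biological explanation of what set that array apart was tested.

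Of 32 monocyte receptors, 12 were lower in HCMV. A lower share of monocytes would lower all receptors alike only if monocytes alone made them, which was not examined. The SD of their log2 fold changes was 4.13 times their median standard error, which argues against a common fall as the whole cause. Regulation of some receptors alone would also give such a spread, so no conclusion on the share is drawn from it. A first criterion also required that FCER1G (0.01), CD68 (0.32) and CSF3R had not fallen together with the rest. CSF3R fell by 0.72 on the log2 scale, so by that criterion the question stayed open too. A change of the share therefore stays open. Under quantile normalization and under centring on the median, 11 of the 12 lower receptors were still lower, which argues against the choice between these scalings as the cause of those calls. A fall of receptor mRNA after infection is a hypothesis that may account for the lower values, and a batch that followed the groups cannot be told apart from infection.

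The treatment text leaves open whether some HCMV samples had received an inhibitor. If an NF-kB inhibitor had blocked the response in some arrays, their NF-kB list mean would lie near the mock arrays, but the lowest HCMV array lay above the highest mock array by 14.4 SD of the HCMV arrays. This argues against a full block of the NF-kB response in any of the 6 arrays. A partial block, such as one shared by all 6 arrays, stays open. An inhibitor that leaves these genes alone, such as one of phosphoinositide kinase, could not be examined this way. Infection as the source of the rise is a hypothesis that these tests leave standing.

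In 34 of 332 groups of 6 arrays, 1 array stood apart from the other 5 by a gap of over 0.625 of the range, where chance gives about 16.6, and 10 of these were in HCMV replicate 2 and 11 in mock replicate 2. In mock replicate 2 the values were low for the NF-kB list (12.25), dendritic cell markers (10.52), CCL2 (9.13), CCL3 (12.16), CXCR3 (10.03), DAD1 (12.86), FPR3 (13.33), ICAM1 (11.39), TGFBI (14.63) and TNF (11.07) and high for TIMP2 (13.52). In HCMV replicate 2, besides the interferon list, the sterol list (10.94), ADAM10 (11.98), CD14 (12.75) and TNFRSF10B (11.28) were low, and the platelet list (13.23), CCR1 (15.93), CLU (15.22), PF4 (15.05) and SOCS1 (13.08) were high. In mock replicate 6 the platelet list (13.22), CLU (15.33) and PF4 (14.74) were high and CASP4 (12.26) was low. The rest were CSF1 (13.69), HLA-DRA (16.75) and TIMP1 (16.80), low in mock replicate 1, MMP1 (6.80), low in mock replicate 4, NINJ1 (13.80), high in mock replicate 5, CCL3 (17.02), low in HCMV replicate 1, and CCRL2 (16.24), NOTCH3 (8.29) and TNF (17.05), high in HCMV replicate 4.

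Of the 67 control probe sets, which were outside the fit, 7 were higher in HCMV, each with an exact p of 0.00216, the smallest the permutation can give, and an adjusted p of 0.0207. The 4 for the interferon signalling factor named ISGF3A on the array were higher by 1.83, 1.98, 2.05 and 2.20 log2, and the 3 for the transferrin receptor by 0.98, 0.83 and 1.02 log2. All 7 were higher in 6 of 6 HCMV arrays than in any mock array.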

How the results depend on the processing

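The alternative without HCMV replicate 2 and mock replicate 2 together was chosen only after the data were seen. Of 85 named genes past the threshold, 82 stayed past it in all 24 alternatives run on them and 0 reversed. The exceptions were CD8B, NCAM1 and SC5D. These genes were picked for large changes or small p in the same data, so their stability does not carry over to the other called genes. Of all 1356 called genes, 1059 were still called without HCMV replicate 2 and mock replicate 2 together. That was the lowest count, with 1091 without HCMV replicate 4, 1217 under quantile normalization and at most 1353 in any alternative. Of the named genes not past it, 13 passed in at least 1 alternative: CCL2, CCR1, CSF1, GAPDH, HLA-DRA, IFNGR2, IRF9, RELB, RHOA, RPS12, SLC4A7, SLC7A11 and SLC7A5. A list that changed direction without being past the threshold in either setting is counted as unchanged. At an adjusted p under 0.01, which is stricter by construction, 400 probe sets and 281 genes were higher and 537 and 415 lower. Centring on the median gave 53.3% lower probe sets and quantile normalization 57.5%, against 61.0%.

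With an estimated correlation the adjusted p was 0.0603 for chemokine ligands, 0.164 for anti-inflammatory mediators and for cytoskeleton genes, 0.0984 for interferon-stimulated genes and 0.069 for monocyte receptors. For monocyte receptors it was also 0.118 at the 60th percentile filter and 0.0634 with averaged probe sets, and 0.0155 to 0.0768 when 1 array was left out. M2 markers passed without a filter (0.0217), with quantile normalization (0.0497), median centring (0.0363), array weights (0.0201), fry (0.00958) and without HCMV 2 and mock 2 (0.00672), and ran from 0.00608 to 0.144 when 1 array was left out. Ribosomal protein genes passed without a filter (0.0117) and with quantile normalization (1.67e-06), and ran from 0.00629 to 0.195 when 1 array was left out. Glycolysis (0.0423) and sterol genes (0.00615) passed with fry, which does not compare a list with other genes. The 3' to 5' difference ran from 0.0747 to 0.117 for GAPDH and from 0.12 to 0.193 for ACTB when 1 array was left out, and was 0.21 for ACTB without HCMV 2 and mock 2. For all of these changes the cause was not tested.

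The replicate numbers did not pair the samples: same-numbered arrays deviated together with r of 0.49, -0.01, 0.25, -0.11, -0.22 and -0.08, and 2 of 6 pairs exceeded 0.1. Only 1 HCMV array and 1 mock array correlated best with its own number. HCMV replicates 2, 3, 4, 5 and 6 correlated best with mock replicates 6, 5, 2, 4 and 5 (r of 0.35, 0.37, 0.19, 0.32 and 0.32). Whether arrays with different numbers share a donor was not tested, and a block by number cannot test it. With the number as a replicate block, 675 probe sets were higher and 979 lower, and 1163 of the 1356 genes were still called. The adjusted p in that paired fit was 0.062 for monocyte receptors, 0.041 for M2 markers and 0.0384 for ribosomal protein genes, and no other pathway list changed its call.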

Other observations

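The gene lists below and their tests were all chosen only after the gene table was seen, so they are not independent evidence. Of 48 genes of oxidative phosphorylation, which make most of the cell's ATP in mitochondria, 17 fell, 1 rose and 30 did not pass, with a median of -0.34 and a camera adjusted p of 0.00144 (adjusted p = 0.086 with an estimated correlation). UQCRC1 (-1.38 ± 0.16) and UQCRB (-0.96 ± 0.19), subunits of complex III, fell, and NDUFV2 (0.84 ± 0.16) rose. Of 10 enzymes of tryptophan and tetrahydrobiopterin metabolism, 4 rose, GCH1 (2.56 ± 0.17), KMO (2.15 ± 0.36), IDO1 (2.12 ± 0.41) and KYNU (0.68 ± 0.13), 0 fell and 6 did not pass, with a camera adjusted p of 0.00218 (adjusted p = 0.086 with an estimated correlation). Of 17 proteasome genes 3 rose, PSMA3 (1.10 ± 0.17), PSMA5 (0.85 ± 0.21) and PSMB7 (0.48 ± 0.15), with a camera adjusted p of 0.00759 (adjusted p = 0.131 with an estimated correlation).

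The 4 other lists did not shift with camera. Of 9 enzymes of leukotriene and prostaglandin synthesis, the leukotriene enzymes ALOX5 (-1.85 ± 0.30), ALOX5AP (-1.28 ± 0.39) and LTA4H (-2.50 ± 0.38) and the thromboxane synthase TBXAS1 (-1.47 ± 0.18) fell and PTGS2 (4.30 ± 0.47) rose (adjusted p = 0.24). Of 25 genes of DNA replication and repair, 7 fell, PCNA (-1.21 ± 0.34) among them, and 1 rose, NBN (2.64 ± 0.25) (adjusted p = 0.131). Of 9 complement components 3 rose, CFB (3.11 ± 0.39), C1QB (1.80 ± 0.40) and SERPING1 (0.71 ± 0.21), and 2 fell (adjusted p = 0.121). Of 15 cytosolic tRNA synthetases 2 rose and 1 fell (adjusted p = 0.18).

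A hypothesis from FUCA1 and other fallen genes is that a lysosomal program may fall after infection. Of 35 lysosomal hydrolases and membrane proteins 12 fell and 3 rose, with a median of -0.41. DNASE2 (-2.51 ± 0.40), GALC (-1.67 ± 0.26) and CTSD (-1.63 ± 0.30) fell, GLA (1.58 ± 0.21) and NPC1 (1.22 ± 0.22) rose, and LAMP1 was at -0.05 ± 0.12. The camera adjusted p was 0.00979 and 0.0691 with an estimated correlation, so the data leave the hypothesis open, and the list held the genes that prompted it.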
